A study of Homo sapiens with 6 samples.

How the data were processed

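RNA was taken with TRIzol from A549 cells grown in DMEM with serum, in 3 libraries of untreated cells and 3 of cells given B35 at 2 µM for 72 h, per the labels. Libraries were made with a NEBNext Ultra RNA kit, per the labels' protocols, and whether counting used strand is not given in the sources used here. Reads were aligned with HISAT2 2.0.5 and counted with featureCounts 1.5.0-p3 on hg38, per the submitters' processing notes. The deposited files hold a whole-number count per gene and an FPKM value per gene, as the authors made them, for 58735 gene identifiers in each library. All 58735 identifiers are in GENCODE release 29, which supplied symbols, coordinates and exon overlaps, and no entry lacked a gene. The FPKM values deposited by the authors were used only as a check. They equal the count per kilobase of merged exon length divided by a number that is 0.982 to 1.05 times each library's total count, and how that number was set is not given in the sources used here.

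Library totals ran from 17141478 to 18530670 counts, so the groups differed little in depth. Replicate libraries differed by more than sampling noise (chi-square per degree of freedom of 4.46 to 32.3 over genes with at least 20 counts), none held identical values, and each was counted as 1 replicate. The correlation of log2 CPM across genes between replicates was 0.983 to 0.992, where genes are not independent replicates.

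Counts were tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16, after filterByExpr (minimum count 10, minimum total 15) and TMM scaling, with library totals recomputed over the kept genes. Factors ran from 0.979 to 1.03. The test was two-sided, p-values were adjusted by Benjamini-Hochberg over 14773 genes, and a gene changed where the adjusted p was under 0.05. CPM values are counts scaled to the usual common total with the TMM factors, given as mean ± SD over 3 libraries. The SE of a log2 fold change is its size divided by the square root of the F statistic. A gene with no count in 1 group has a fold given as a bound against 3 counts over that group, which covers counting error only.

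Gene lists were tested with camera from limma 3.58.1, with a preset correlation of 0.01, for lists with at least 5 tested members. Of 1063 listed symbols 1062 matched a gene. The gene lists, the tests and the alternatives, except where stated, were fixed before the data were examined. So was the rule for named genes. It took KDM1A, the 12 largest rises and 12 largest falls among genes that passed with a mean CPM of 1 or more, a standard symbol and no overlap between groups, and the 5 smallest adjusted p-values in each direction. It also took up to 4 members per list that passed, in order of adjusted p, or, where none passed, the 2 with the highest CPM. ABCG1, MXI1, AK4, CA12, NR1H3, TPM1, PGAM1, PKM and FOSB were chosen after their values were seen. Some genes that the rule took are not reported here. Overlapping genes named as sharing exons could share reads.

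The test was run on simulated data drawn from the means and library sizes of these 6 libraries, with 14554 genes in the fit. It recovered 43.94% of genes changed 1.5-fold, 82.26% of those changed 2-fold and 96.92% of those changed 4-fold, with 3 false calls among 146. In a simulation of lists over 14773 genes, camera called 6 of 6 lists moved by a log2 shift of 0.4 and none of 30 unmoved lists. Its genes were drawn independently, so it cannot show how often camera calls unmoved lists whose members are correlated. In the data the estimated correlation reached 0.718, in the mitochondrially encoded list.

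Alternatives were relative log expression and upper-quartile scaling, no filter beyond 1 count in total, a mean CPM of 1 or more, each library left out in turn, the replicate number as a term, robust dispersion, glmTreat against 1.5-fold, DESeq2 1.42.0 and limma-voom. For lists they were an estimated correlation and fry. Removal of each library's trend on GC content and exon length by offsets was added after seeing the data. Tables and plots used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.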

Results

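RNA sequencing measured gene expression in A549 cells, an established human line from a non-small cell lung cancer. The cells received B35 at 2 µM for 72 h or were left untreated for the same time, with 3 libraries in each group. The series names B35 as an inhibitor of LSD1, the histone demethylase encoded by KDM1A, and the comparison addresses how the compound alters gene expression. The labels name no solvent in the untreated cultures, and they do not say whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries. The deposited gene counts summed to 18339021, 18398450 and 17141478 in the control libraries and to 17209863, 18002425 and 18530670 in the B35 libraries. A count was recorded for 21077 to 21554 genes per control library and for 21464 to 22365 genes per B35 library. The first principal component of the log2 CPM (counts scaled to a common library total) held 48.5% of the variance and separated the groups. The next held 20.9% and set B35 replicate 1 apart from the other B35 libraries.

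Of 14773 genes tested, 2276 changed with B35, of which 1303 rose and 973 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Changes of at least 2-fold were seen in 453 genes, 394 higher and 59 lower with B35, as the plot of fold change against expression level shows. Most of these genes were expressed at a low level, with a median of 2.71 CPM among those that rose by 2-fold and 24.9 CPM among all genes tested. The number of changed genes was 1079, 1286 and 881 without control replicates 1, 2 and 3 in turn, and 3342 without B35 replicate 1. These fits use fewer libraries, and none of the 2276 genes changed sign in them. Here and below, rises and falls in such a fit count the genes that passed the test in it. With each library's trend on GC content and gene length removed, an alternative chosen after seeing the data, 4028 genes changed, 1853 higher and 2175 lower, and 2253 of the 2276 genes were among them.

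**Figure D1:**
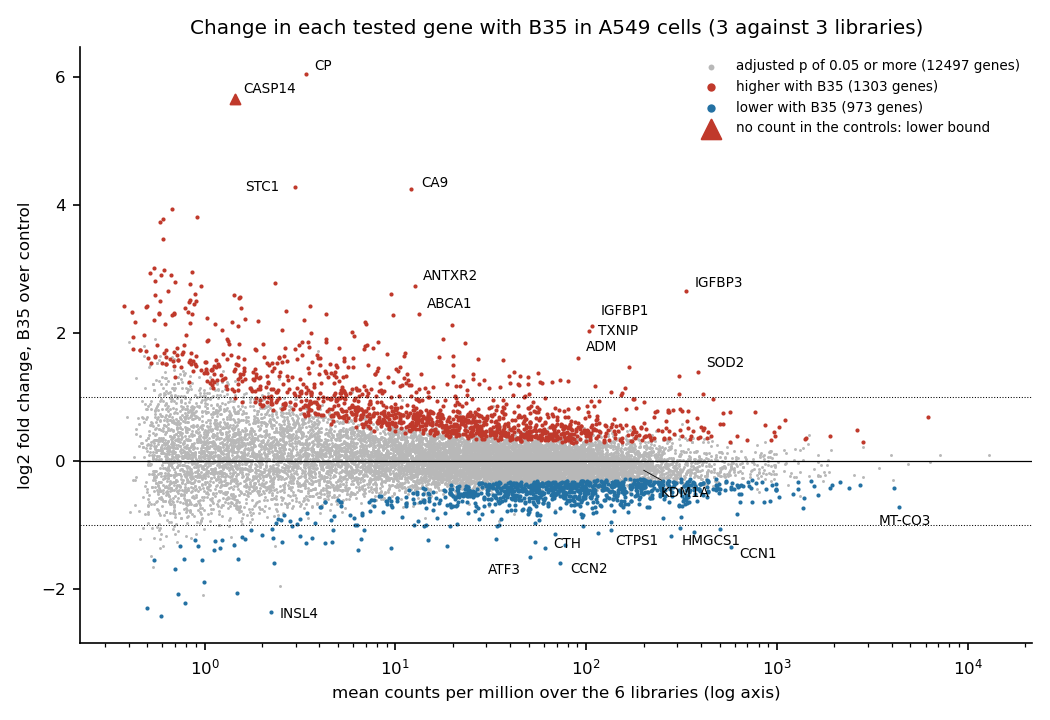
Each point is 1 of the 14773 tested genes, with its mean CPM over the 6 libraries on a log axis and its log2 fold change (B35 over control, 3 libraries each) on the other axis. Red and blue points are the 1303 genes that rose and the 973 that fell, dotted lines mark 2-fold, and the triangle is the lower bound for CASP14, which had no count in the controls.

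KDM1A, the gene of the enzyme that B35 is said to inhibit (ENSG00000004487, chromosome 1, 23019443 to 23083689, plus strand, hg38), did not pass the test. It was measured at 198 ± 2.56 CPM in control cells and 184 ± 8.97 CPM in B35 cells (SD, n = 3 each). Its log2 fold change was −0.11 ± 0.084 (SE, edgeR adjusted p = 0.432), and the level of this transcript is no measure of the enzyme's activity. Among 17 tested genes of the LSD1-CoREST complex and its partners, 3 rose and none fell. The clearest was ZNF217, a zinc finger protein found with CoREST, at 1.5-fold (log2 0.59 ± 0.094, edgeR adjusted p = 0.00306), in a gene that shares exon positions with AL157838.1. The calls of ZMYM3 and PHF21A, the other members that rose, were lost when any 1 control library was left out (edgeR adjusted p between 0.0599 and 0.0984), and that of ZMYM3 also without B35 replicate 2 (0.0637). Adjusted over the list alone, 4 members rose and 2 fell, and the list did not shift as a set (camera adjusted p = 0.493). With the GC and length trends removed, 3 members rose and 3 fell, and without B35 replicate 1, 3 rose and 1 fell.

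Other chromatin regulators changed in single members. KDM5B, a histone H3 demethylase, was the only 1 of 16 tested H3K4 methyltransferases and demethylases that passed, at 1.46-fold (log2 0.55 ± 0.10), and it was also the only 1 adjusted over the list alone. With the GC and length trends removed, 2 members of that list fell. Among 19 tested Polycomb and DNA methylation genes, 1 rose and 3 fell. UHRF1, which recruits the maintenance methyltransferase to replicated DNA, was 1.53-fold lower, and DNMT1, that methyltransferase, was 1.39-fold lower in a gene that shares exons with S1PR2. CBX7, a Polycomb reader protein, was 1.65-fold higher. Adjusted over the Polycomb and methylation list alone, 1 rose and 5 fell, and neither list shifted as a set (camera adjusted p = 0.784 and 0.222). Without B35 replicate 1, 3 members of the Polycomb and methylation list rose and 4 fell. Of the myeloid genes known from LSD1 inhibition in leukaemia, only 2 of 13 had enough counts to test, and ITGAX rose from 0.799 to 2.43 CPM (log2 1.6 ± 0.37, edgeR adjusted p = 0.0163). Of neuronal genes repressed by REST, 2 of 12 rose, UNC13A by 2.26-fold and KCNH2 by 2.77-fold, and the list did not pass (camera adjusted p = 0.222, with 2 members also higher adjusted over the list alone). UCHL1 rose by 2.20-fold and was the only 1 of 4 tested neuroendocrine genes to pass over all genes, while 2 rose adjusted over the list alone.

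The largest rises were in genes with few or no counts in control cells. CASP14, a caspase of keratinocyte differentiation (chromosome 19, 15049384 to 15058293), had no count in the controls and 157 counts in the B35 libraries, which is at least 50.5-fold higher against a floor of 3 counts over the group. CP, encoding the copper carrier ceruloplasmin, rose from 0.095 ± 0.086 to 6.72 ± 3.14 CPM (SD, n = 3 each). Its control value rests on 5 reads, and it shares exons with HPS3. STC1, a secreted glycoprotein, rose by 19.5-fold (log2 4.28 ± 0.43), and the genes next in size among those with a mean of at least 1 CPM were CA9, LINC00520, ANTXR2, IGFBP3, LUCAT1, VNN1, HAL, PRDM8 and IFI27, with log2 fold changes from 4.26 down to 2.43. LUCAT1 is a long noncoding RNA annotated as antisense, and the counts are not stated to use strand. IGFBP3, which binds insulin-like growth factors (chromosome 7, 45912245 to 45921874), rose from 91.2 ± 5.27 to 574 ± 63.3 CPM. TXNIP, an inhibitor of thioredoxin and of glucose uptake, rose from 40.7 ± 1.11 to 167 ± 4.19 CPM. IGFBP1 rose by 4.35-fold and ABCA1, a cholesterol exporter, by 4.93-fold (edgeR adjusted p = 1.08e-06 and 1.85e-05).

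The falls were smaller in size. INSL4, a hormone of the insulin family (chromosome 9, 5231419 to 5235304), dropped from 3.74 ± 0.722 to 0.730 ± 0.0567 CPM, which is 5.08-fold lower. CCN2 and CCN1, matricellular proteins induced by mechanical and growth signals, were 3.0-fold and 2.54-fold lower, and CCN1 was abundant in control cells at 820 ± 96.0 CPM. The stress-induced transcription factor ATF3 was 2.82-fold lower, the orphan nuclear receptor NR4A3 2.55-fold lower, and CHAC1, which degrades glutathione, 2.49-fold lower. STXBP6 was 2.60-fold lower. TAGLN, an actin-binding protein of smooth muscle, was 2.99-fold lower in a gene that shares exons with PCSK7. The pseudogenes PDCD6IPP1 and SNRPGP10 also fell (log2 −2.06 ± 0.36 and −1.52 ± 0.33), and both could share reads with their parent genes. SNRPGP10 lost its call without control replicate 1 or 3 (edgeR adjusted p = 0.0531 and 0.0561). ICOSLG, an immune costimulatory ligand at 2.60-fold lower, lost its call without control replicate 1, control replicate 2 or B35 replicate 2 (edgeR adjusted p = 0.104, 0.0782 and 0.0775). The smallest p-values among falls belonged to CTPS1, which makes CTP for nucleic acid synthesis (2.11-fold lower), HMGCS1 (2.25-fold) and the small heat shock protein HSPB8 (2.17-fold), each with edgeR adjusted p = 8.58e-05.

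Of 45 gene lists fixed before the data were examined, 42 had at least 5 tested members and 19 shifted as a set, 13 up and 6 down (camera with its preset correlation of 0.01, Benjamini-Hochberg over the lists). With the correlation estimated from the residuals, 2 of the 19 held. With fry, a rotation test of each list on its own, 22 lists passed. In the other splits of the 6 libraries, which mix control and B35 libraries, preset camera still called 5 to 14 lists. An estimated correlation and fry called none there. A call with the preset correlation alone is thus weak evidence of a shift with B35. The calls of the 19 lists were kept when any 1 library was left out. The plot of list members shows their log2 fold changes.

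**Figure D2:**
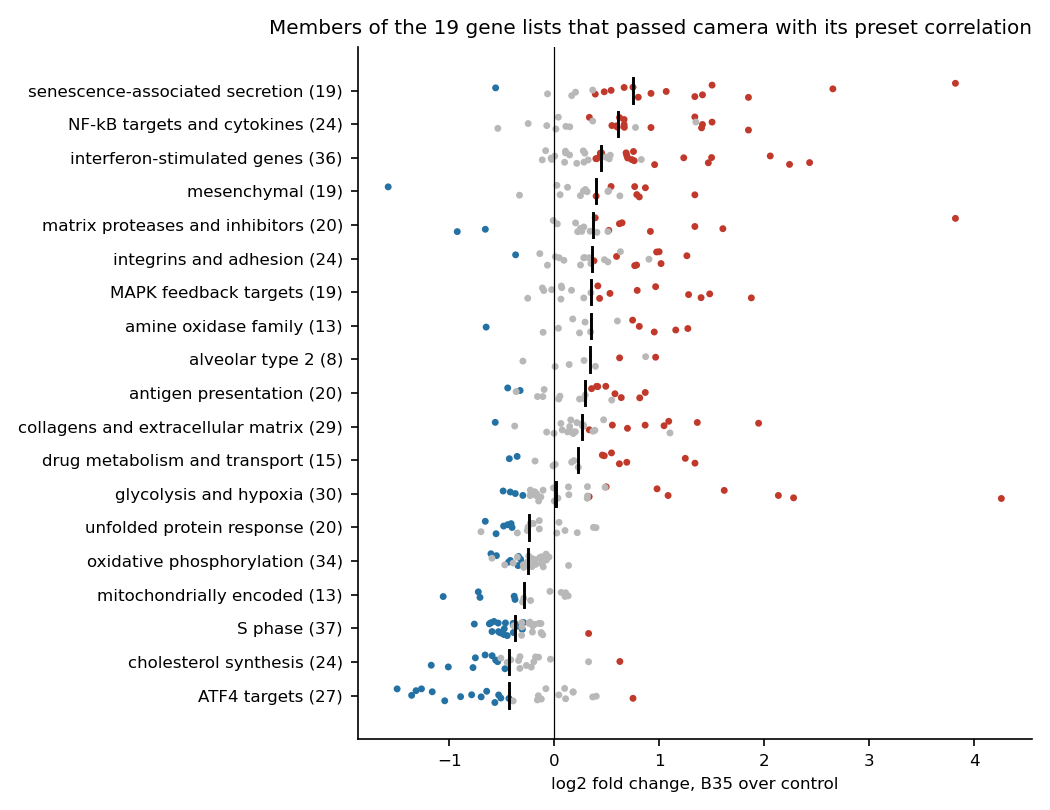
Each point is a tested member of 1 of the 19 lists that passed camera with its preset correlation, placed by its log2 fold change (B35 over control, 3 libraries each). Red and blue points passed the edgeR test, grey points did not, the black bar is the list's median, and the number of tested members stands in brackets. The medians run from −0.43 for ATF4 targets to 0.75 for senescence-associated secretion.

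Some secreted and inflammatory genes rose. The list named senescence-associated secretion also holds genes whose products are not secreted, such as CDKN1A and LMNB1. Of its 19 tested genes, 14 rose and 1 fell, and the counts were the same adjusted over the list alone. This list kept its call with an estimated correlation (camera adjusted p = 2.61e-18 preset and 0.0241 estimated). Members that rose included IGFBP3, the neutrophil chemokine CXCL8 (3.61-fold) and the cytokine IL1B (2.66-fold). Of 24 tested NF-kB targets and cytokines, 14 rose and none fell (15 adjusted over the list alone), and this list also held (camera adjusted p = 7.63e-11 preset and 0.0329 estimated). SOD2, the mitochondrial superoxide dismutase, rose from 210 ± 13.7 to 557 ± 33.6 CPM in a gene that shares exons with WTAP, and IL1A rose by 2.84-fold. The lists share members, among them CXCL8, IL1A and IL1B. The rises numbered 9 in each list without control replicate 1, and 9 among NF-kB targets without control replicate 3.

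Some interferon-stimulated genes and genes of antigen presentation rose with B35. Of 36 tested interferon-stimulated genes, 18 rose and none fell (23 adjusted over the list alone, camera adjusted p = 5.63e-10 preset and 0.137 with an estimated correlation). The antiviral enzymes OAS2 and OAS1 rose by 2.83-fold and 1.69-fold, IFI27 by 5.4-fold, and IFIT2, in a gene that shares exons with LIPA, by 1.62-fold. Without control replicates 1, 2 and 3 in turn, 12, 11 and 11 members rose. Of 20 tested genes of antigen presentation, 8 rose and 2 fell (10 and 2 adjusted over the list alone, camera adjusted p = 0.00356 preset and 0.404 with an estimated correlation). The class I genes HLA-E, HLA-B and HLA-F rose by 1.76-, 1.56- and 1.82-fold. These genes are similar in sequence, HLA-B shares annotated exons with HLA-C and HLA-F with HLA-F-AS1, so reads could be split between them. The rises in this list numbered 5 without control replicate 1 or 3 and 11 without B35 replicate 1. The falls numbered 1 without control replicate 1 or B35 replicate 3 and none without control replicate 2, control replicate 3 or B35 replicate 2.

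Some genes that respond to low oxygen rose, while several glycolytic enzymes fell. The list of glycolysis and hypoxia genes had 8 of 30 members higher and 4 lower, the 4 being glycolytic enzymes (10 and 4 adjusted over the list alone). CA9, a carbonic anhydrase of hypoxic tumours (chromosome 9, 35673856 to 35681159), rose from 1.18 ± 0.459 to 22.9 ± 6.88 CPM and shares exons with ARHGEF39. The vasodilator peptide gene ADM rose by 3.07-fold, the prolyl hydroxylase EGLN3 by 4.86-fold and ANGPTL4, an inhibitor of lipoprotein lipase that shares exons with RAB11B-AS1, by 4.39-fold. As a set the list shifted up (camera adjusted p = 0.000566 preset and 0.352 with an estimated correlation), with a mean log2 fold change of 0.39 and a median of 0.017. Without control replicates 1, 2 and 3 in turn, 1, 2 and no members fell, and 12 rose and 8 fell with the GC and length trends removed. The median was below 0 without control replicate 3, B35 replicate 2 or B35 replicate 3.

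Some genes of the cell surface and the extracellular matrix rose. Of 24 tested integrins and adhesion molecules, 8 rose and 1 fell (16 and 1 adjusted over the list alone, camera adjusted p = 2.38e-06 preset and 0.261 with an estimated correlation). They included the collagen receptor subunit ITGA2 at 2.40-fold, the protocadherin PCDH1 at 2.02-fold, the fibronectin receptor subunit ITGA5 at 1.70-fold and the laminin receptor subunit ITGB4 at 1.72-fold. The rises among integrins numbered 6 without any 1 of the controls, 12 without B35 replicate 1 and 12 with the GC and length trends removed. The member that fell lost its call, without a change of sign, without control replicate 2, control replicate 3 or B35 replicate 2 and with upper-quartile scaling. Of 20 matrix proteases and inhibitors, 8 rose and 2 fell (10 and 2 adjusted over the list alone, camera adjusted p = 2.71e-06 preset and 0.272 with an estimated correlation). The protease inhibitor SERPINE2 rose by 3.05-fold, and the collagenase MMP1 rose from 0.115 ± 0.0614 to 1.70 ± 0.0453 CPM (SD, n = 3 each). Of 29 collagens and matrix genes, 8 rose and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p = 0.000765 preset and 0.473 with an estimated correlation), among them the laminin chain LAMB3 at 2.07-fold and ECM1 at 1.62-fold. THBS1 was 1.48-fold lower in a gene that shares exons with FSIP1. The rises in the matrix list numbered 4, 5 and 2 without control replicates 1, 2 and 3, and 5 and 4 without B35 replicates 2 and 3. The falls in it numbered 2 without control replicate 1 or with the GC and length trends removed.

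Of 19 tested mesenchymal genes, 7 rose and 1 fell (9 and 2 adjusted over the list alone, camera adjusted p = 1.96e-05 preset and 0.261 with an estimated correlation). TGFBI (1.72-fold), ITGA5 and fibronectin, FN1 (1.83-fold), were among the rises, and the member that fell was TAGLN. The rises in this list numbered 5 to 9 with 1 library left out, and 2 members fell with the GC and length trends removed. Of 18 epithelial genes, 4 rose and 1 fell, and that list did not shift as a set (camera adjusted p = 0.331). The tight junction genes CLDN1 and CLDN4 rose by 1.82-fold and 1.79-fold, the placental cadherin CDH3 by 3.03-fold and the adhesion molecule EPCAM by 2.14-fold. Adjusted over the list alone, 5 epithelial genes rose and 3 fell, and over all genes 5 rose and 4 fell without B35 replicate 1 and 4 rose and 2 fell without B35 replicate 2. The rises and falls were equal, 5 each, with the GC and length trends removed. In a list of amine oxidases of several enzyme families, 5 of 13 rose and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 0.0019 preset and 0.196 with an estimated correlation). The members that rose included the lysyl oxidases LOXL4 (1.94-fold), LOX (2.23-fold) and LOXL2 (1.75-fold), secreted copper-dependent enzymes that cross-link collagen and do not share the flavin-dependent domain of LSD1. Of these, LOX shares exons with SRFBP1 and LOXL2 with ENTPD4. Spermine oxidase, SMOX, was 1.57-fold lower.

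Feedback targets of MAPK signalling rose in 9 of 19 tested genes, with none lower (10 adjusted over the list alone, camera adjusted p = 3.25e-08 preset and 0.196 with an estimated correlation). The ETS factors ETV4 and ETV5 rose by 2.64-fold and 1.95-fold, IER3 by 2.79-fold and the ERK phosphatase DUSP6 by 2.43-fold, and ETV4 shares exons with DHX8. The rises numbered 5 without control replicate 1 and 6 without control replicate 3, and 1 member fell without B35 replicate 1. Immediate early genes moved in both directions, with 6 of 19 higher and 7 lower (6 and 8 adjusted over the list alone) and no shift as a set (camera adjusted p = 0.273). FOS fell from 328 ± 8.37 to 178 ± 25.1 CPM, and NR4A3 and ATF3 were lower too, while JUN rose from 195 ± 12.7 to 342 ± 36.1 CPM (SD, n = 3 each). The rises in this list numbered 2 without control replicate 1 or 3 and 3 without control replicate 2 or B35 replicate 3. TGF-beta targets also went both ways, 8 higher and 5 lower of 25 (10 and 5 adjusted over the list alone, camera adjusted p = 0.372), with TGFBI higher and CCN1 and CCN2 lower. The rises numbered 5 without control replicate 1, control replicate 2 or B35 replicate 2, and the falls 3, 3 and 2 without control replicates 1, 2 and 3. Of 22 WNT pathway genes, 6 rose and none fell, the same counts as adjusted over the list alone, among them DKK1 (1.53-fold), WNT5A (1.44-fold) and WNT11 (4.87-fold), and that list did not pass (camera adjusted p = 0.0784) except without B35 replicate 1 (0.0404). Without any 1 of the controls 3 of them rose. NOTCH3 rose by 2.51-fold, and the 20 tested NOTCH pathway genes, with 2 higher and 2 lower (4 and 2 adjusted over the list alone), did not shift as a set (camera adjusted p = 0.292). In this list 1 rose and none fell without any 1 of the controls, 2 rose and 1 fell without B35 replicate 2, and 4 rose without B35 replicate 1, with upper-quartile scaling or with the GC and length trends removed.

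Some genes of DNA replication fell, and genes of mitosis did not pass the test. Of 37 tested S phase genes, 22 fell and 1 rose (28 and 1 adjusted over the list alone, camera adjusted p = 9.61e-12 preset and 0.200 with an estimated correlation). The replication factor MCM10 fell from 50.9 ± 1.89 to 30.0 ± 1.72 CPM, the licensing factor CDC6 was 1.43-fold lower, UHRF1 1.53-fold and the helicase subunit MCM6 1.41-fold lower. The falls numbered 10, 14 and 9 without control replicates 1, 2 and 3 and 13 without B35 replicate 3. The list's median log2 fold change was −0.3707 with all libraries and ran from −0.4229 to −0.3217 with 1 library left out. The S phase gene that rose lost its call, without a change of sign, without any 1 of the controls, without B35 replicate 2 and with the GC and length trends removed. None of 39 tested G2 and mitosis genes passed with the edgeR test, also adjusted over the list alone, and the list did not shift as a set (camera adjusted p = 0.372). At an unadjusted threshold of 0.05, 6 were higher and 1 lower, DESeq2 called 1 and limma-voom none. The topoisomerase TOP2A was at 468 ± 69.8 CPM in control cells and 521 ± 66.9 CPM with B35, and the proliferation marker MKI67 at 350 ± 15.8 and 388 ± 60.9 CPM, differences smaller than the larger SD. Without B35 replicate 1, 3 of the 39 genes rose and 1 fell, and with the GC and length trends removed 5 rose.

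The p53 targets did not shift as a set (camera adjusted p = 0.794), with 5 of 28 higher and 4 lower (6 and 4 adjusted over the list alone). GDF15, a stress cytokine, rose by 1.68-fold, and SESN2, AEN and the p53 phosphatase PPM1D were 1.86-, 1.61- and 1.43-fold lower. The median of this list was −0.038 and its mean 0.023, and 2 and 1 members rose without control replicates 1 and 3. Of 29 apoptosis regulators, 4 rose and 6 fell (5 and 9 adjusted over the list alone, camera adjusted p = 0.319). Cytochrome c, CYCS, was 1.93-fold lower and CASP9 1.6-fold lower, while the BH3-only gene BMF rose by 2.41-fold. Without control replicate 2 or 3, 2 members rose and 2 fell, without B35 replicate 1, 6 rose and 6 fell, and with the GC and length trends removed 5 rose and 9 fell.

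Part of the cholesterol synthesis genes and of the ATF4 targets fell. Of 24 tested cholesterol synthesis genes, 10 fell and 1 rose (14 and 1 adjusted over the list alone, camera adjusted p = 1.68e-10 preset and 0.200 with an estimated correlation). HMGCS1, which makes HMG-CoA, fell from 385 ± 9.30 to 171 ± 18.1 CPM in a gene that shares exons with AC114947.2. IDI1, FDFT1 and MSMO1, enzymes further down the pathway, were 2.01-, 1.58- and 1.45-fold lower, and with 1 library left out the falls numbered 10 to 13 and the rises none to 2. With the GC and length trends removed 17 fell. ABCG1, a cholesterol exporter chosen after its values were seen, rose by 2.42-fold, as did ABCA1 by 4.93-fold. Of 27 ATF4 targets, the genes of the amino acid response, 14 fell and 1 rose (15 and 3 adjusted over the list alone, camera adjusted p = 2.66e-09 preset and 0.261 with an estimated correlation). Cystathionine gamma-lyase, CTH, fell from 87.9 ± 2.73 to 34.3 ± 5.81 CPM, and the serine synthesis enzymes PSPH and PSAT1 were 2.40-fold and 2.06-fold lower. The falls among ATF4 targets numbered 10 to 14 with 1 library left out. The rises numbered 4 without B35 replicate 1, 2 without control replicate 2 or with upper-quartile scaling, and 3 with the GC and length trends removed. Of 20 genes of the unfolded protein response, 6 fell and none rose (9 and 2 adjusted over the list alone, camera adjusted p = 0.00856 preset and 0.352 with an estimated correlation). The chaperone HSPA5 was 1.33-fold lower, a call lost without control replicate 2 or 3 (edgeR adjusted p = 0.0724 and 0.0879). The falls in that list numbered 3 without control replicate 1, 2 without B35 replicate 2 and none without control replicate 2 or 3. Its median log2 fold change was −0.2386 with all libraries and −0.2675, −0.1963 and −0.2318 without control replicates 1, 2 and 3. Without B35 replicate 3, 7 fell and 1 rose, and with the GC and length trends removed 9 fell and 1 rose.

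Some genes of mitochondrial respiration fell with B35, in the nuclear and in the mitochondrial genome. Of 34 nuclear genes of oxidative phosphorylation, 8 fell and none rose (9 adjusted over the list alone, camera adjusted p = 9.26e-06 preset and 0.433 with an estimated correlation). ATP5F1B, a subunit of ATP synthase, was 1.35-fold lower, a call lost without control replicate 3 (edgeR adjusted p = 0.0606). The falls numbered 1, 2 and none without control replicates 1, 2 and 3, and 2 without B35 replicate 3. They numbered 11 without B35 replicate 1, where 1 member rose, and 14 with the GC and length trends removed. The list's median log2 fold change was −0.2526 with all libraries. It was −0.2402, −0.2283 and −0.2631 without control replicates 1, 2 and 3, and −0.1555, −0.3638 and −0.2333 without B35 replicates 1, 2 and 3. Of 13 mitochondrially encoded genes, 5 fell and none rose, the same counts as adjusted over the list alone (camera adjusted p = 0.000759 preset and 0.473 with an estimated correlation). MT-ND3 fell from 680 ± 15.4 to 327 ± 62.6 CPM, and MT-CO3 and MT-CYB were 1.63-fold and 1.65-fold lower, with MT-CO3 sharing exons with MT-ATP6. Without B35 replicate 1, 8 of these genes fell, and without any other 1 library 3 fell. The share of counts on the mitochondrial ribosomal RNAs moved the other way, from 0.525 ± 0.0466% in control cells to 0.837 ± 0.168% in B35 cells (SD, n = 3 each). The share on mitochondrial messenger RNAs was 4.17% in B35 replicate 1, above the controls (3.62% to 3.74%), and 3.12% and 2.83% in B35 replicates 2 and 3.

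Fatty acid genes went both ways, 4 of 25 higher and 4 lower (5 and 5 adjusted over the list alone, camera adjusted p = 0.746), with ATP citrate lyase, ACLY, 1.61-fold lower, ACSL5 1.63-fold higher in a gene that shares exons with ZDHHC6, and the pyruvate dehydrogenase kinase PDK4 1.62-fold higher. Of 26 NRF2 targets, 2 rose and 7 fell (3 and 11 adjusted over the list alone, camera adjusted p = 0.292). The transporter ABCC3 rose by 2.99-fold and AKR1C1, similar in sequence to its paralogs, by 2.38-fold. The falls among NRF2 targets numbered 2, 3 and 1 without control replicates 1, 2 and 3 and 2 without B35 replicate 3, and without B35 replicate 1 the rises numbered 5. The falls among fatty acid genes numbered 2, 1 and 1 without the controls in turn, and 1 and 2 without B35 replicates 2 and 3, while 6 rose and 8 fell with the GC and length trends removed. Of 15 genes of drug metabolism and transport, 7 rose and 2 fell, the same counts as adjusted over the list alone (camera adjusted p = 0.00338 preset and 0.196 with an estimated correlation). They included CYP1B1 at 2.53-fold, which shares exons with CYP1B1-AS1 and RMDN2, ALDH3B1 at 1.46-fold, the retinoic acid hydroxylase CYP26B1 at 1.54-fold and the efflux pump ABCG2 at 1.37-fold. Without control replicate 2 or 3 the rises numbered 4. The falls numbered 1 without control replicate 1, control replicate 2, B35 replicate 2 or B35 replicate 3 and none without control replicate 3.

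Among lung lineage genes, the alveolar type 2 list shifted up, with 2 of 8 tested genes higher (5 adjusted over the list alone, camera adjusted p = 0.00522 preset and 0.254 with an estimated correlation). They were ETV5, which is also a MAPK feedback target, and the cathepsin CTSH at 1.54-fold, and neither is a surfactant gene. Without B35 replicate 1 or with upper-quartile scaling, 4 members rose. The type 1 list did not pass (camera adjusted p = 0.213), with 2 of 12 genes higher (4 adjusted over the list alone), among them COL4A3 at 2.51-fold. In that list 1 gene rose without control replicate 3, 3 rose without B35 replicate 3, 3 rose and 1 fell without B35 replicate 1, and 4 rose and 1 fell with the GC and length trends removed. In the airway list 1 of 6 rose, also adjusted over the list alone, the gel-forming mucin MUC5AC, from 1.43 ± 0.854 to 5.81 ± 1.71 CPM (camera adjusted p = 0.0553). That list passed without control replicate 2 or B35 replicate 2 (0.0101 and 0.0181), and 2 members rose without B35 replicate 1. Of 9 tested gut and liver genes, 2 rose and 1 fell (4 and 1 adjusted over the list alone), with the protease inhibitor SERPINA1 at 6.96-fold from a level of 0.169 CPM (camera adjusted p = 0.149). Without control replicate 2 or 3, 1 of these genes rose and none fell, and without B35 replicate 2 or 3 none fell. Without B35 replicate 1, 3 rose, and with upper-quartile scaling 3 rose and none fell. Of 19 immune and blood cell genes 2 could be tested, and neither passed with the edgeR test, also adjusted over the list alone, with 1 higher at an unadjusted 0.05 and none called by DESeq2 or limma-voom. MARCO, a macrophage receptor, had an edgeR adjusted p of 0.153 and passed as higher without B35 replicate 1 (0.0352). The 17 untested genes of that list had 16 counts in the controls and 41 in the B35 libraries. Of 16 fibroblast and endothelial genes 5 could be tested, and none passed over all genes, while 3 fell adjusted over the list alone (camera adjusted p = 0.149), the same number as at an unadjusted 0.05, and DESeq2 and limma-voom called none. The list's most abundant member was COL1A1 at 25 ± 0.735 and 19.9 ± 0.998 CPM (edgeR adjusted p = 0.0596). With the GC and length trends removed, 2 members of this list fell, COL1A1 among them (edgeR adjusted p = 0.00576), and without B35 replicate 1, 1 fell.

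The remaining lists did not shift as a set. Of 47 cytosolic ribosomal protein genes 1 fell, RPS12 at 1.36-fold, a call lost without control replicate 1, 2 or 3 (edgeR adjusted p = 0.164, 0.084 and 0.104) or B35 replicate 3 (0.0936). None passed adjusted over the list alone. That list had a camera adjusted p of 0.104, and it passed as lower without B35 replicate 2 (0.000689), where 3 members fell and 1 rose, the same counts as with the GC and length trends removed. Of 32 autophagy and lysosome genes, the cathepsin CTSB was 1.41-fold higher and the proton pump subunit ATP6V0D1 1.45-fold lower, the same counts as adjusted over the list alone (camera adjusted p = 0.794). Without B35 replicate 1, 2 of them rose and 2 fell, and 3 fell with the GC and length trends removed. Of 13 histone genes of the replication-dependent kind, 2 rose (3 rose and 1 fell adjusted over the list alone), with H2BC21 at 1.73-fold (camera adjusted p = 0.493). The rises numbered 1 without control replicate 2, control replicate 3, B35 replicate 2 or B35 replicate 3, and 1 histone gene fell without B35 replicate 1 or 2, with relative log expression scaling and with the GC and length trends removed. Within a histone class these genes are similar in sequence, and most of their transcripts lack the poly(A) tail. None of 5 tested cancer-testis genes passed, also adjusted over the list alone (camera adjusted p = 0.649), with 1 higher and 1 lower at an unadjusted 0.05 and none called by DESeq2 or limma-voom. The most abundant were MAGEA1 at 58.5 ± 4.17 and 53.5 ± 3.12 CPM and MAGEA6, a close paralog of other MAGEA genes, at 83.0 ± 2.47 and 68.2 ± 7.23 CPM. With the GC and length trends removed MAGEA6 passed as lower (edgeR adjusted p = 0.0119). Of 6 stem cell genes 2 rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.292), with MYC and CD44 at 1.28-fold and 1.32-fold, and both lost their calls without any 1 of the controls (edgeR adjusted p of 0.0518 to 0.0957 for MYC and 0.0608 to 0.0914 for CD44). Without B35 replicate 2, 3 of the stem cell genes rose. The stem cell gene that fell lost its call without control replicate 1, control replicate 3, B35 replicate 2 or B35 replicate 3. The plot of single genes gives CPM per library for genes of the main groups.

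**Figure D3:**
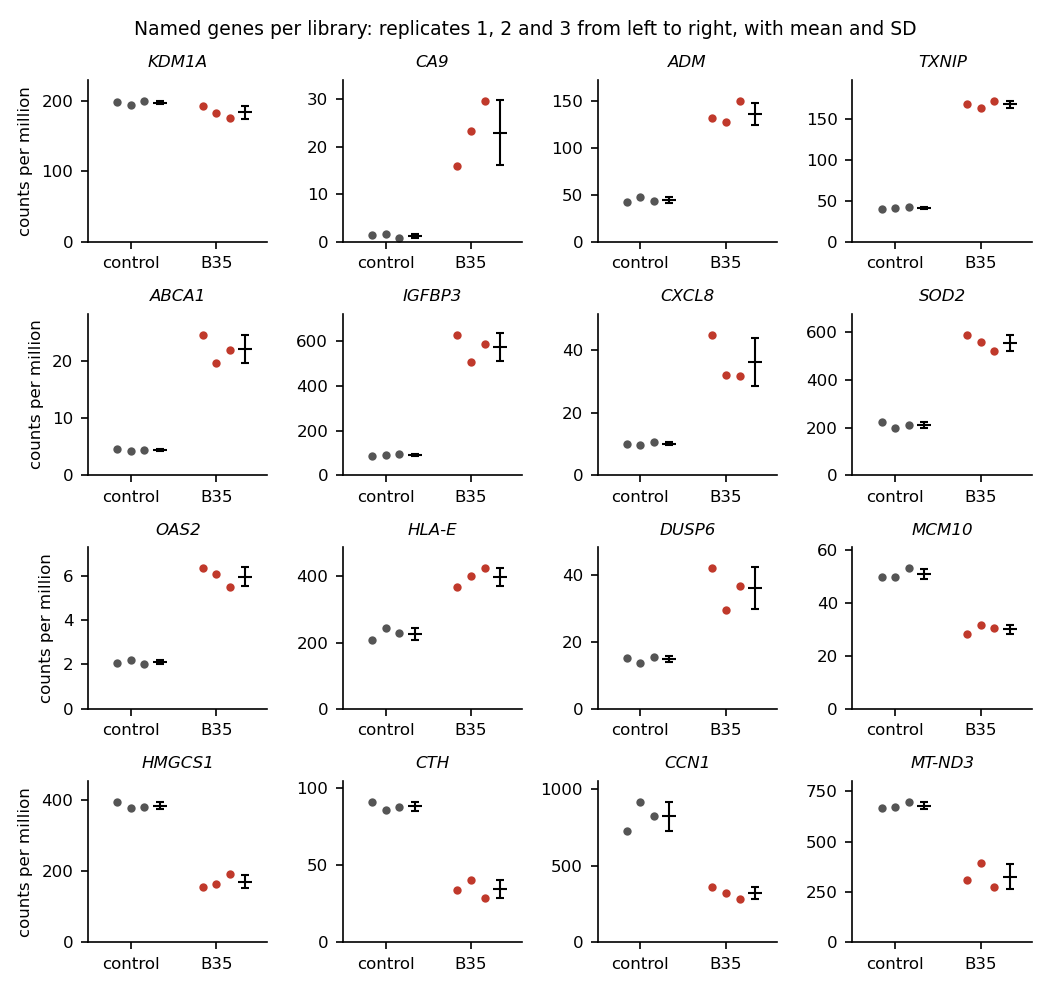
CPM of 16 named genes in each library, with controls in grey and B35 in red, replicates 1, 2 and 3 from left to right, and the mean with its SD (n = 3) beside them. The axes start at 0, and in each gene the B35 libraries lie apart from the control libraries. All but KDM1A were taken by rules that asked for a passed test, so their separation is no further evidence. In KDM1A the difference did not pass the test (edgeR adjusted p = 0.432). Of all tested genes 36.32% had no overlap between the groups, with 10% expected by chance, so its separation alone is no sign of a change.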

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

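Removing the trends on GC content and length was chosen only after the results were seen; the other alternatives were planned. With 1 library left out, the number of changed genes ran from 881 (without control replicate 3) to 3342 (without B35 replicate 1), the rises from 587 to 1822 and the falls from 294 to 1520. These fits use fewer libraries. With GC and length trends removed 4028 genes changed and 2175 fell, and the cause was not tested further than for B35 replicate 1. Other scalings, filters, robust dispersion, DESeq2 and limma-voom gave 2196 to 2895 changed genes. None of the 2276 genes changed sign in any setting that gave it a value. DESeq2 gave no adjusted p for 62 of them and called 2117 of the other 2214. Changes of at least 2-fold numbered 312 to 514 with 1 library left out. A test against a fold of 1.5 itself (glmTreat), which asks for more by construction, gave 176 genes, 151 higher and 25 lower.

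With the replicate number as a term (replicate block) 2855 genes changed, 2237 of them among the 2276. The labels do not say whether equal numbers pair the samples. Deviations of same-numbered libraries correlated at 0.163, 0.0162 and −0.063, and control replicate 2 correlated most with B35 replicate 3 (0.249). With 3 libraries in each group these correlations cannot tell whether the numbers pair the samples. KDM1A did not pass in any setting, with log2 fold changes from −0.15 to −0.07.

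With an estimated correlation 2 of 19 lists held. The adjusted p-values of the other 17 were 0.1963 for amine oxidases, MAPK feedback and drug metabolism; 0.2613 for mesenchymal genes, ATF4 targets and integrins; 0.2001 for S phase and cholesterol synthesis; and 0.1369 for interferon-stimulated genes. They were 0.4044 for antigen presentation, 0.3519 for glycolysis and hypoxia and for the unfolded protein response, 0.4329 for oxidative phosphorylation and 0.4731 for mitochondrially encoded genes and for collagens. For alveolar type 2 genes it was 0.2536 and for matrix proteases 0.2724. By fry 16 of the 19 held, and oxidative phosphorylation (0.0748), mitochondrially encoded genes (0.1202) and collagens (0.1058) did not, and the cause was not tested. The 19 lists kept their calls under the scalings, filters, replicate block, GC and length offsets and each left-out library. At this depth and number of libraries 43.94% of simulated 1.5-fold changes were found. The simulation made 146 calls against 2276 in the data, so its cutoff after adjustment was stricter. The share of small changes missed in the data is thus not known.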

Other observations

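The test of glycolytic enzymes and the shifts of all B35 values were chosen only after results were seen. So were the olfactory interval between libraries and the removal of GC and length trends. The lists of HIF, LXR, YAP-TEAD and SRF targets were chosen after the first changed genes were seen but before their own members' values. The camera p-values of these lists and of the glycolytic enzymes are not adjusted over lists, unlike those of the fixed lists.

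Several genes that respond to low oxygen rose with B35, and a candidate explanation is a HIF response. Of 20 HIF targets outside the fixed list 7 rose and none fell, among them MXI1 (log2 1.37 ± 0.15), AK4 (1.23 ± 0.16) and CA12 (0.87 ± 0.11), with camera p = 5.135e-06 preset and 0.0273 with an estimated correlation. Lower oxygen in the B35 cultures predicts higher glycolytic enzymes, and so does a HIF response of any cause that reaches these enzymes. Their median log2 fold change was −0.1718 (SE 0.078 over 15 genes, which are not independent), and 4 fell and none rose. As a set these enzymes shifted down with the preset correlation (camera p = 0.01222) and had camera p = 0.344 with an estimated correlation. PGAM1 and PKM lost their calls without control replicate 3 (edgeR adjusted p = 0.0635 and 0.0604) and PGAM1 also without control replicate 1 (0.0561). An action of the compound on these genes by another route stays open and untested, since oxygen was not measured.

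Among changes of at least 2-fold, 86.98% were rises. Even background such as genomic DNA would raise silent genes alike, but 849 olfactory receptor genes with too few counts to be tested gained 0.0005027 CPM per kilobase (95% counting interval 2.482e-05 to 0.0009807, and 1.137e-05 to 0.0009896 from the spread between 3 libraries each). The 25th percentile of the genes raised at least 2-fold was 0.276. Any receptor gene with enough counts to be tested was left out of this comparison. The share of rises argues against the low level of these genes as the cause, since 79.8% of the 99 such changes at 10 CPM or more were rises. Its 95% interval, 70.54 to 87.2, counts each gene as an independent trial, which genes are not, so it may be too narrow. The scaling stays open. The lowest share under the other scalings was 86.09%, but these moved the median log2 fold change by at most 0.0288, too little to decide. Lowering all B35 values by a log2 shift of 0.3, in steps of 0.05, brought the share to 51.05% and the changed genes from 2276 to 6108. A large enough shift must lower the share, so this gives only the size of error that would be needed. No biological explanation was tested.

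B35 replicate 1 lay apart on the second principal component, and leaving it out raised the count of changed genes from 2276 to 3342. Its counts, relative to the other libraries, fell with GC content (Spearman −0.486 across 9845 genes) while those of B35 replicates 2 and 3 rose (0.343 and 0.495). The control libraries had trends too (−0.363, 0.289 and −0.104), and control replicate 1, whose trend had the same sign, lowered the count to 1079 when left out. With such trends removed, leaving out B35 replicate 1 gave 3972 genes against 4028 (ratio 0.9861), so the gain was gone, consistent with a library trend as part of its reason. Leaving out the other libraries then gave 0.686, 0.714 and 0.599 of the 4028 for the controls and 0.896 and 0.815 for B35 replicates 2 and 3. B35 replicate 1 thus stayed the library whose loss lowered the count least, and what else sets it apart was not tested. Whether the trend arose in library preparation or sequencing was not tested.

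ABCA1 and ABCG1 rose while cholesterol synthesis genes fell, and activation of the sterol-sensing LXR receptors may account for the exporters. The 6 other tested LXR targets all lay above 0 and 2 rose (camera p = 0.01304 preset and 0.0637 with an estimated correlation), and 1 of these, NR1H3, lost its call without control replicate 2 or 3 (edgeR adjusted p = 0.0512 and 0.0622). CCN1 and CCN2 fell, and the 23 other YAP-TEAD targets left lower YAP-TEAD activity undecided (camera p = 0.2828 preset and 0.536 with an estimated correlation). Of these, 3 rose and 5 fell. TAGLN, FOS and FOSB fell, with lower SRF activity as a candidate explanation. Of 14 other SRF and actin genes 3 fell, among them TPM1, and none rose (camera p = 0.0007631 preset and 0.068 with an estimated correlation). The LXR and SRF lists passed only with the preset correlation, so both explanations stay undecided.

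The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 2276 changed genes, 453 of at least 2-fold and 19 lists, and the highest of the other splits gave 1, 1 and 14. In each case 1 of the 10 splits, the real one, gave a result as large. All the other splits gave 5 to 14 lists with preset camera and none with an estimated correlation or fry. The real split gave 2 lists with an estimated correlation and 22 with fry. Each other split sets 2 libraries of a group against 1, so part of the difference between control and B35 stays in it. The lists called there may partly reflect it. The mixing also adds that difference to the spread within each side, which lowers the number of changed genes whatever caused the difference. The gene counts of these splits thus cannot decide.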
